A study of Mus musculus with 4 samples.

How the data were processed

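Per the labels, each library came from sorted mouse bone marrow cells of the LSK gate (Lin−Sca-1+Kit+, the stem and early progenitor gate), pooled from 5 mice aged 8 to 12 weeks. Per the series' design text, Kit+ cells were enriched with beads before sorting, and Vav1-iCre switched on the mutant alleles in blood-forming cells. The labels define 4 genotypes with 1 library each: control (Vav1-iCre alone), Ikk2CA (a constitutively active Ikk2), Jak2V617F, and a double mutant with both alleles.

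Per the series' design text, reads were aligned and counted with Cell Ranger 3.0.1, whereas per the file headers the deposited matrices were written by Cell Ranger 4.0.0. The submitters' processing notes name the mm10 genome build and Seurat 4.0.0. The deposited values are counts: whole unique molecular identifiers (UMIs) per gene and barcode, not normalised, for 32285 genes per the file headers. Neither the reporter nor the recombinase was among these features. Gene coordinates are from the GENCODE annotation of GRCm38, the assembly behind mm10.

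Barcodes were kept with the filter of the authors' design text, 500 to 7500 genes and under 10% mitochondrial UMIs. This left 37344 of 41674 barcodes. For each library the UMIs of all kept cells were summed per gene and scaled to the library total as CPM. Genes with at least 10 CPM in either library of a comparison were compared. With 1 library per genotype no test across libraries was made, although a model without an interaction would have left 1 residual degree of freedom, so no p-value is given and ratios are descriptions of these libraries. Intervals are 95%, exact Poisson for a sum of UMIs, exact conditional binomial for a ratio and exact binomial (Clopper-Pearson) for a share, and they cover counting error only. A gene with 0 UMIs in a library was put at a floor of 3 UMIs.

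Genes were named by a rule fixed beforehand. Candidates had at least 20 CPM in either library and excluded mitochondrial, cytosolic ribosomal protein, unnamed, antigen receptor and sex-linked genes. For each mutant against control the 12 highest and 12 lowest ratios were named, for the double mutant against each single mutant the 6 highest and 6 lowest, and for the departure from additivity the 6 most positive and 6 most negative. Not all of these genes are described here, and highest and lowest ratios below are ranks among these candidates. Up to 4 members of each described list with the largest absolute log2 ratio could be named as well, with all sort markers, sex-linked genes and engineered loci.

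Of 37 gene lists fixed beforehand, those other than the sort markers, sex-linked genes and engineered loci were summarised by the median log2 ratio of members with at least 10 CPM in any library. Each median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a percentile. That percentile describes these libraries and is not a test. Departure from additivity was the log2 CPM of the double mutant minus both single mutants plus control. Correlations of effects were taken across genes, which are not independent replicates.

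Cells of the 4 libraries were clustered together: counts scaled to 10000 per cell, log-transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1. A cluster was named after a cell type when at least 3 markers fixed beforehand stood among its 25 leading genes and its 10 leading genes held more of them than of any other type's. A cluster with Xist among its 10 leading genes was given no cell type, whatever its markers. The naming rule was chosen after the clusters had been seen. A cluster led by immunoglobulin genes was kept apart, and the rest stayed unnamed. Class-standardised sums weighted each class by its share of control cells. Unnamed clusters and classes with under 20 cells in any library were pooled for this. Scrublet was run per library and its calls were kept in the main results. It called 211 cells, under 0.5% in 3 of the 4 libraries, so it did not work there. An added alternative left out the cells with the highest scores, 0.8% per 1000 barcodes, or 3351 cells.

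TMM and median-of-ratios factors were computed with edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3 as alternative scalings only. In a self-test on Ikk2CA against control, simulated Poisson counts with planted changes put 67 of 67 genes changed 3-fold and 66 of 66 changed 4-fold past 2-fold, with 0 of 67 changed 1.5-fold and 0 of 7699 unchanged. Of 200 random lists, 9 (4.5%) fell outside the middle 95%. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.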

Results

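The data were 4 droplet single-cell RNA libraries of LSK bone marrow cells, the gate that holds blood stem cells and early progenitors, from control, Ikk2CA, Jak2V617F and double-mutant mice. Ikk2CA is a constitutively active form of the kinase that switches on NF-κB, and Jak2 V617F is the activated kinase of myeloproliferative disease. After filtering, 8055 control, 9865 Ikk2CA, 14156 Jak2V617F and 5268 double-mutant cells remained, which were 81.0%, 95.5%, 90.6% and 91.2% of the deposited barcodes. The mitochondrial limit removed 1727 control barcodes, against 381, 1416 and 439 in the mutants in that order. Depth differed between the libraries, with a median of 10606 UMIs per control cell, 17726 per Ikk2CA cell, 11106.5 per Jak2V617F cell and 24915 per double-mutant cell. The sums behind each level were 102362297, 197836491, 182778171 and 142211877 UMIs. There was 1 pooled library per genotype, so differences between animals could not be measured, and intervals cover counting error only.

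The pools differed in sex. Xist, the transcript of the inactive X chromosome (mm10 chrX:103460366-103483254), was at 1176 CPM in control, 250.2 CPM in Ikk2CA, 0.257 CPM in Jak2V617F and 319.8 CPM in the double mutant. Among cells with at least 5000 UMIs, 41.5%, 75.7%, 99.6% and 70.9% had no Xist UMI. Its antisense partner Tsix was at 32.1, 15.9, 5.02 and 12.1 CPM. The Y-linked genes Ddx3y (24.9, 27.4, 49.3 and 26.2 CPM), Eif2s3y (29.1, 40.4, 47.5 and 37.6 CPM), Kdm5d (9.49, 10.3, 18.2 and 9.58 CPM) and Uty (8.09, 9.73, 18.8 and 8.52 CPM) were highest in Jak2V617F. Of the sort markers, Ly6a, which encodes Sca-1, was at 106.0, 233, 138 and 191 CPM, and Ly6e at 606, 1464, 704 and 1198 CPM. Kit was at 149, 87.6, 175 and 93.5 CPM, Cd34 at 429, 190.4, 331 and 264 CPM, Slamf1 at 4.15, 2.56, 8.21 and 6.05 CPM, Cd48 at 141, 184, 144 and 205 CPM, and Flt3 at 144, 59.4, 92.3 and 51.2 CPM. Of the genes listed as engineered loci, Ikbkb was at 58.4, 53.9, 67.3 and 51.5 CPM, Jak2 at 19.8, 15.6, 18.0 and 11.6 CPM, and Vav1 at 50.1, 39.2, 37.1 and 36.0 CPM. These levels do not distinguish mutant from normal alleles. The genotype labels do not say at which loci the Ikk2-CA and iCre sequences lie, so they need not be readouts of altered loci.

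In Ikk2CA cells, NF-κB target genes, immediate early genes and B cell genes were higher than in control, and stem cell genes were lower. The median log2 ratio of 31 NF-κB targets was 0.62, at percentile 100 of random lists, with 25 above 0. It was led by the chemokine Ccl5 (75.5 against 8.98 CPM), the NF-κB subunit Relb (34.9 against 6.31 CPM), the inhibitor Tnfaip3 (19.5 against 4.16 CPM) and the feedback inhibitor Nfkbia (325 against 69.9 CPM). All 17 measured stress and immediate early genes were higher (median 1.05, percentile 100), among them Nr4a1 (25.9 against 2.28 CPM), Nr4a2 (22.7 against 2.79 CPM), Fos (411 against 55.7 CPM) and Fosb (112 against 23.6 CPM). All 16 measured haematopoietic stem cell genes were lower (median −1.09, percentile 0).

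Among the stem cell genes, the transcription factor Hlf was at 43.4 CPM against 220.8 CPM in control, Trim47 at 5.35 against 16.1 CPM and Mecom at 14.5 against 43.4 CPM. Within stem cell-like cells assigned from the control library, described below, Mecom differed far less between these libraries, while Hlf stayed clearly lower. The B cell list had a median log2 ratio of 2.43 (0.34 class-standardised) with 10 of 10 above 0, including Igkc, Pax5 (18.4 against 3.17 CPM), Vpreb3 (263 against 45.9 CPM) and Cd79a (187 against 32.9 CPM). B cell-like cells made up 14.6% of this library against 1.97% of control. The dendritic list, with a median of 1.96 (1.06 with genes of at least 50 CPM), held Ly6d (411 against 25.8 CPM) and Siglech (11.1 against 0.977 CPM), and in the lymphoid priming list (median −0.09, or 0.15 with TMM factors) Ebf1 (273 against 52.2 CPM) and Jchain (737 against 167 CPM) were higher. Interferon-stimulated genes were lower (median −0.61, percentile 0), with Ifit1 at 4.54 against 15.6 CPM and Rsad2 at 4.92 against 15.7 CPM. The STAT5 and JAK-STAT feedback list had a median of −0.12 (percentile 86.2; 0.12 with TMM factors), with the cyclin Ccnd1 at 70.6 against 27.3 CPM and the feedback gene Cish at 7.08 against 11.1 CPM. Quiescence genes had a median of 0.46, with Klf4 at 16.7 against 2.73 CPM, Klf2 at 47.1 against 10.3 CPM and Txnip at 89.5 against 244 CPM.

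Among kept cells, the largest ratios of Ikk2CA over control were those of the globin genes Hbb-bs (35.8-fold, 444 against 12.4 CPM), Hba-a2 (28.9-fold) and Hba-a1 (26.1-fold), followed by the endosomal trafficking gene Ehd3 (mm10 chr17:73804134-73832094; 19.5-fold, interval 17.2 to 22.2). Over all deposited barcodes the log2 ratios of Hbb-bs, Hba-a2 and Hba-a1 were 3.61, 3.22 and 3.61 (5.16, 4.85 and 4.71 among kept cells), and that of Hbb-bs was 1.14 without the cells of highest doublet score. Ly6d was 15.9-fold higher, the eosinophil granule gene Prg2 14.5-fold (log2 ratio 3.86, or 2.78 over all deposited barcodes), Nr4a1 11.4-fold, the histone gene Hist1h2ap 9.85-fold, Ccl5 8.41-fold (log2 ratio 3.07, or 4.37 in cells with no Xist UMI and 3.73 with lineage clusters left out), Gimap4 8.18-fold, Nr4a2 8.11-fold and the inhibitor of differentiation Id3 7.45-fold. The log2 ratio of Prg2 was 4.93 as a mean over cells scaled to the same total and 4.68 in cells with no Xist UMI. The lowest were the sialomucin Emcn (0.142 of control) and Wfdc17 (24.3 against 157 CPM), with Paqr5 at 0.172, the lipoprotein receptor Vldlr at 0.194 and Hlf at 0.196 of control. They were followed by Shisa8 (0.267), Mycn (0.269), Hacd4 (0.270), Nfia (0.303) and Zfp760 (0.311). From bound to bound, the counting intervals of the 24 highest and lowest ratios, not all described here, spanned at most a factor of 1.31. Of 8377 genes, 179 were at least 2 times as high and 282 at most 0.5 times as high as in control. The median gene was at a log2 ratio of −0.23, and counted relative to it the numbers were 244 and 127, close to the 248 and 123 with TMM factors. Relative to that median, the list medians were 0.85 for NF-κB targets, 1.28 for stress genes, 2.66 for B cell genes, 0.69 for quiescence genes, −0.86 for stem cell genes and −0.38 for interferon-stimulated genes.

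**Figure D1:**
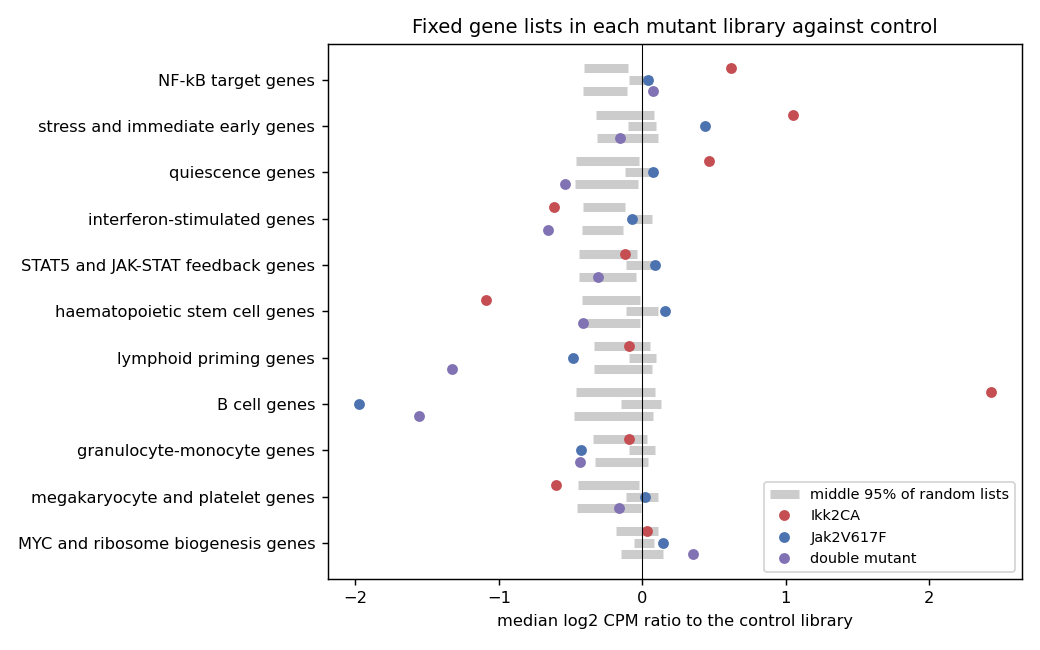
Median log2 CPM ratio of gene lists fixed beforehand, for each mutant against control. In Ikk2CA the B cell list was at 2.43 and the stem cell list at −1.09, and in Jak2V617F the B cell list was at −1.97.

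In the Jak2V617F library, lymphoid and B cell genes were lower than in control, and immediate early genes were higher. Some JAK-STAT feedback genes were higher as well, while the median of their list stayed within the middle 95% of random lists. The B cell list had a median log2 ratio of −1.97 (percentile 0, 0 of 10 above 0), or −0.43 class-standardised, and the lymphoid priming list −0.48 (percentile 0, 2 of 19 above 0). Immediate early genes had a median of 0.44 (percentile 100, 15 of 17 above 0). The STAT5 and JAK-STAT feedback list had a median of 0.09 (percentile 96.2, 14 of 19 above 0), with the suppressors of cytokine signalling Socs2 (17.5 against 8.89 CPM) and Socs3 (12.1 against 6.46 CPM), the cyclin Ccnd1 (46.4 against 27.3 CPM) and the kinase Pim2 (14.7 against 8.74 CPM). NF-κB targets had a median of 0.04 (percentile 90.7).

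The lowest ratios were those of Jchain, the immunoglobulin joining chain (mm10 chr5:88519809-88527891; 18.8 against 167 CPM, ratio 0.113, interval 0.108 to 0.117; log2 ratio −3.15, or −2.21 as a mean over cells scaled to the same total), and the pre-B cell genes Vpreb3 (0.203 of control), Cd79a (0.217), Igll1 (0.226), Ebf1 (0.261), Mzb1 (0.267) and Vpreb1 (0.286). Jchain is a leading gene of the immunoglobulin-led cluster, a very small share of either library, and its interval does not measure spread between cells. The interleukin-7 receptor Il7r was at 0.368, the carbonic anhydrase Car1 at 0.378 (log2 ratio −1.40, or −0.57 with lineage clusters left out), Bfsp2 at 0.439, Dntt, which adds bases at antigen receptor joints, at 0.441 and Ly6d at 0.445 of control. B cell-like cells were 0.657% of this library against 1.97% of control, and with class-standardised sums the log2 ratios of Vpreb3, Cd79a, Igll1, Ebf1, Mzb1, Vpreb1 and Bfsp2 were −0.61, −0.61, −0.43, −0.31, −0.55, −0.24 and −0.28. The highest ratios were those of Hbb-bs (5.64-fold), Fosb (3.84-fold, 90.7 against 23.6 CPM), Hist1h2ap (3.76-fold), Fos (3.15-fold, 176 against 55.7 CPM), Hba-a1 (3.12-fold), Egr1 (3.02-fold), the clock gene Per1 (2.89-fold) and Selp, a platelet adhesion receptor (2.78-fold, 28.5 against 10.3 CPM). Over all deposited barcodes the log2 ratios of Hbb-bs and Hba-a1 were −0.30 and −0.67, so their direction rests on the barcode filter. Klf2 was 2.38-fold higher, Serpina3g 2.35-fold (226 against 96.2 CPM), Hist1h3c 2.30-fold and Hist1h4h 2.08-fold.

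Stem cell genes had a median log2 ratio of 0.16 (percentile 99.8), with Gata2 at 84.1 against 61.2 CPM and Hoxb4 at 25.4 against 19.2 CPM. The granulocyte-monocyte list was lower (median −0.43, percentile 0, 1 of 23 above 0), with the elastase Elane at 245 against 502 CPM and the transcription factor Cebpa at 19.1 against 33.4 CPM. The megakaryocyte list was at 0.02 (−0.055 class-standardised), the erythroid list at −0.13 (0.34 with genes of at least 50 CPM), interferon-stimulated genes at −0.07 (0.048 with genes of at least 50 CPM), and MYC and ribosome biogenesis genes at 0.14 (percentile 100). Of 8405 genes, 25 were at least 2 times as high and 38 at most 0.5 times as high. The counting intervals of the 24 ratios spanned at most a factor of 1.17.

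In double-mutant cells, a core of NF-κB targets was higher than in control, lymphoid and interferon-stimulated genes were lower, and immediate early genes were near the control level. NF-κB targets had a median log2 ratio of 0.07 (0.31 relative to the median gene at −0.24, percentile 100, but −0.12 with genes of at least 50 CPM), with Ccl5 at 42.8 against 8.98 CPM, Relb (mm10 chr7:19606217-19629438) at 28.9 against 6.31 CPM and Nfkbia at 252 against 69.9 CPM, whereas the chemokine Ccl3 was at 9.20 against 36.8 CPM. The lymphoid priming list had a median of −1.32 (−1.09 relative, percentile 0), with Jchain at 19.5 against 167 CPM, Blnk at 3.10 against 15.2 CPM and Il7r at 6.22 against 21.5 CPM. The B cell list had a median of −1.56 (−1.32 relative, −0.47 class-standardised), and B cell-like cells were 0.930% of the library. Interferon-stimulated genes had a median of −0.66 (−0.42 relative, percentile 0), with Ifi44 at 7.55 against 24.2 CPM and Rsad2 at 5.35 against 15.7 CPM.

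Among candidates with at least 20 CPM in either library, the highest ratios in the double mutant over control were those of Ehd3 (10.0-fold, interval 8.82 to 11.5), the protease inhibitor Serpina3f (7.74-fold), Hist1h4d (5.78-fold), the platelet factor Pf4 (5.12-fold, 509 against 99.3 CPM), Ccl5 (4.77-fold), Hba-a2 (4.68-fold), the PD-1 ligand Pdcd1lg2 (4.65-fold), Hbb-bs (4.60-fold), Relb (4.59-fold), Hist1h2an (4.49-fold), Hist1h2ab (3.69-fold) and Hist1h3f (3.63-fold). The log2 ratio of Ccl5 was 1.62 as a mean over cells scaled to the same total and 3.82 in cells with no Xist UMI (2.25 in the main sums), and that of Hba-a2 was 1.45 over all deposited barcodes (2.23). The log2 ratio of Hbb-bs was 1.39 over all deposited barcodes, −0.57 without the cells of highest doublet score and −0.92 in cells with no Xist UMI. The lowest were Car1 (0.112 of control, 16.1 against 144 CPM), Jchain (0.117), Paqr5 (0.183), Wfdc17 (0.198), Ccl3, Vpreb3 (0.271), Il7r (0.290), Mzb1 (0.296), the class II chaperone gene H2-Ob (0.296), Ifi44 (0.311), 9930111J21Rik2 (0.315) and Dntt (0.318). Class-standardised, the log2 ratios of Vpreb3 and Mzb1 were −0.79 and −0.92 (−1.88 and −1.76 in the main sums). That of Jchain was −9.25 without the cells of highest doublet score (−3.10), which left no immunoglobulin-led cells in this library. The Jchain level of the double mutant thus rested almost wholly on those cells. In cells with no Xist UMI the log2 ratios were −2.49 for Jchain, −3.34 for Paqr5 (−2.45) and −3.40 for Wfdc17 (−2.34). In the mast cell list, the chymase Cma1 was at 18.0 against 1.15 CPM and Mcpt4 at 12.0 CPM against 1 UMI in control (ratio 1232, interval 221 to 48700).

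Stem cell genes in the double mutant had a median of −0.41 (−0.18 relative, percentile 3.07), with 0 of 16 above 0, including Hlf at 74.5 against 220.8 CPM and Procr at 11.7 against 26.1 CPM. The STAT5 and JAK-STAT list had a median of −0.31 (−0.08 relative, percentile 26.2, and 0.01 with median-of-ratios factors), while Socs2 was at 24.6 against 8.89 CPM. MYC and ribosome biogenesis genes had a median of 0.35 (0.59 relative, percentile 100), with Ldha at 562 against 385 CPM and Nhp2 at 306 against 211 CPM. Stress and immediate early genes had a median of −0.16 (0.08 relative, percentile 28.1), with Jund at 110.0 against 174 CPM, and this median was 0.09 with TMM factors and 0.17 with median-of-ratios factors. Quiescence genes had a median of −0.54 (−0.30 relative), with Tob1 at 7.20 against 15.1 CPM. Of 8294 genes, 69 were at least 2 times as high and 202 at most 0.5 times as high as in control, or 116 and 95 relative to the median gene and 122 and 91 with TMM factors. The counting intervals of the 24 ratios spanned at most a factor of 1.30.

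Adding Jak2V617F to Ikk2CA went with lower immediate early, B cell and erythroid genes and higher stem cell genes. Relative to Ikk2CA, the double mutant had lower values for all 17 stress and immediate early genes (median log2 ratio −1.54, percentile 0), with Nr4a1 at 1.58 against 25.9 CPM and Fos at 56.4 against 411 CPM. All 16 stem cell genes were higher in the library sums (median 0.50, percentile 100; 0.30 class-standardised), led by Mecom (32.5 against 14.5 CPM), Trim47 (11.2 against 5.35 CPM) and the adhesion gene Esam (11.9 against 6.62 CPM). Within stem cell-like cells assigned from the control library, however, Mecom was lower in the double mutant (92.5 against 115 CPM), as was Hlf (236 against 257 CPM). The B cell list had a median of −4.00 (−0.98 class-standardised), with B cell-like cells at 0.930% against 14.6%, and the erythroid list −0.69, with Hbb-bs at 57.0 against 444 CPM. NF-κB targets had a median of −0.37 (percentile 0), with Ccl4 at 15.5 against 109 CPM and Tnfaip3 at 7.07 against 19.5 CPM.

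Among candidates with at least 20 CPM in either library, the 6 highest ratios over Ikk2CA were those of Mecom (2.23-fold, interval 2.13 to 2.34), Otos (2.23-fold), Mycn (2.23-fold), Nutf2-ps1 (2.18-fold), Socs2 (2.17-fold) and Phpt1 (2.15-fold). The 6 lowest of these candidates were Prg2 (0.0138 of Ikk2CA, 1.27 against 91.5 CPM), Jchain (0.0265), Mzb1 (0.0402), Id3 (0.0456), Vpreb3 (0.0473) and Ly6d (0.0573). Class-standardised, the log2 ratios of Vpreb3 and Mzb1 were −1.06 and −3.32 (−4.40 and −4.64 in the main sums), without the cells of highest doublet score those of Jchain and Prg2 were −11.06 and −8.32 (−5.24 and −6.18), and with lineage clusters left out that of Socs2 was 1.97 (1.11). The STAT5 and JAK-STAT list had a median of −0.03 (0.02 with median-of-ratios factors), MYC and ribosome biogenesis genes 0.28 (28 of 28 above 0) and megakaryocyte genes 0.25 (13 of 15 above 0), with Selp at 14.5 against 4.87 CPM. Of 7752 genes, 27 were at least 2 times as high and 160 at most 0.5 times as high.

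Adding Ikk2CA to Jak2V617F went with higher levels of some NF-κB targets and lower immediate early, interferon-stimulated and stem cell genes. The 6 highest ratios of the double mutant over Jak2V617F were those of Ehd3 (8.47-fold), Pf4 (5.91-fold), Relb (4.48-fold), the lymphotoxin Ltb (3.45-fold, 304 against 88.0 CPM), Pdcd1lg2 (3.41-fold) and the interleukin-18 receptor Il18r1 (3.28-fold). The 6 lowest were Egr1 (0.282 of Jak2V617F, 17.5 against 62.1 CPM), Fosb (0.295), Car1 (0.297), Ccl3 (0.303), Fos (0.321) and Ccl4 (0.324). NF-κB targets had a median log2 ratio of 0.05, or 0.27 relative to the median gene at −0.21 (percentile 100), but −0.14 with genes of at least 1 CPM, and stress genes −0.79 (−0.57 relative, percentile 0). Stem cell genes were at −0.62 (−0.41 relative), with 0 of 16 above 0, and interferon-stimulated genes at −0.65 (−0.44 relative). The STAT5 and JAK-STAT list was at −0.46 (−0.24 relative, percentile 1.68), with Socs3 at 5.20 against 12.1 CPM and Cish at 8.98 against 18.0 CPM. Of 8247 genes, 59 were at least 2 times as high and 93 at most 0.5 times as high, or 81 and 35 relative to the median gene and 86 and 30 with TMM factors.

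The Ikk2CA allele went with differences in the same direction for many genes in both Jak2 backgrounds, and the Jak2V617F allele did so less closely. Across 8536 genes, the log2 ratio of Ikk2CA over control and that of the double mutant over Jak2V617F, which share no library, had a Pearson correlation of 0.524 and a Spearman correlation of 0.640, against −0.0150 for the Pearson correlation in counts simulated without an effect. Those simulated counts gave every library the same profile, so they do not cover differences tied to depth. Both libraries with Ikk2CA were deeper per cell than their partners (17726 against 10606 and 24915 against 11106.5 median UMIs). A part of the correlation that went with depth cannot be told apart from the allele. With no low-count filter the Pearson correlation of the Ikk2CA effect in both Jak2 backgrounds was 0.289. Of the 8088 genes measured in both, 34 were at least 2 times as high in both, where 0.795 would be shared by independent choice. Of the 119 genes at least 2 times as high without Jak2V617F, 9 were at most 0.5 times as high with it. Those shared included Relb, Nfkbia, Nfkb2, Ltb, Ccl5, Ehd3, Pf4, Pdcd1lg2, Il18r1 and Cd74. At most 0.5 times as high in both were 41 genes (2.48 by independent choice), including Hlf, Procr, Vldlr, Mmrn1, Txnip and Ifi44. For the Jak2V617F effect with and without Ikk2CA, the Pearson correlation was 0.295 and the Spearman correlation 0.0930, against 0.0218 for the Pearson correlation in counts simulated without an effect. The Pearson correlation of the Jak2V617F effect in both Ikk2 backgrounds was 0.105 with lineage clusters left out and 0.119 with no low-count filter. Lower in both were 21 genes (0.403 by independent choice), including Jchain, Dntt, Il7r, Ebf1, Vpreb1 and Car1, and higher in both were 3 genes, Selp, Nupr1 and Hoxb3os, whereas 12 of the 23 genes higher without Ikk2CA were at most 0.5 times as high with it. The main effects of both alleles, each averaged over both backgrounds, had a Pearson correlation of −0.272 and a Spearman correlation of −0.0474, against 0.256 and 0.229 in counts simulated without an effect. The simulated values hold counting error alone, with a covariance of 0.000155 against −0.0400 in the data. Counting error thus added almost nothing to −0.272, and 0.256 is not a baseline for it. The Pearson correlation of the main effects was −0.121 with lineage clusters left out, −0.156 with no low-count filter and −0.171 class-standardised.

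**Figure D2:**
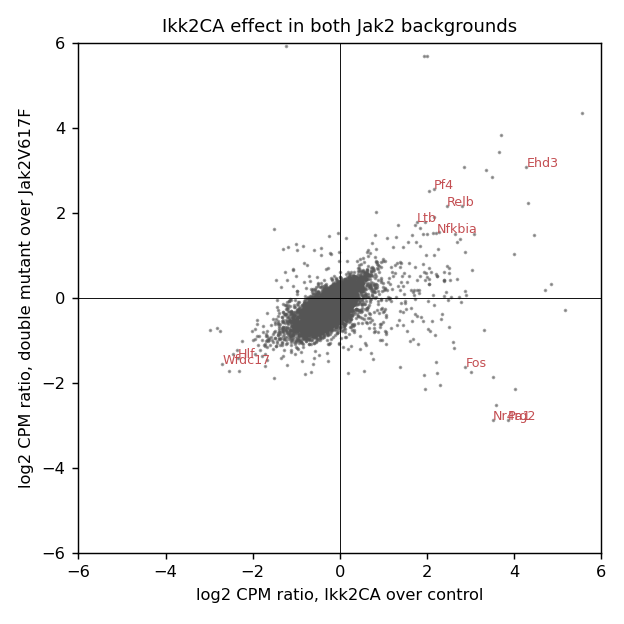
Log2 CPM ratio of each gene for Ikk2CA against control (horizontal) and for the double mutant against Jak2V617F (vertical). Pearson's r across genes was 0.524, and 5 genes lie outside the axes.

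The departure from additivity was most negative for immediate early, globin and eosinophil genes that were highest in Ikk2CA, and among kept cells the 6 named here were also higher in Jak2V617F than in control. Prg2 departed by −6.73, Nr4a1 by −6.39, Hbb-bs by −5.46, Nr4a2 by −4.78, Hba-a2 by −4.54 and Fos by −4.52 (log2). Hbb-bs and Hba-a2 departed by −1.92 and −0.66 over all deposited barcodes, but by −8.09 and −8.02 in cells with no Xist UMI. Prg2 departed by −5.26 without the cells of highest doublet score and by −8.98 as a mean over cells scaled to the same total. Most positive were Emcn (2.12, or 1.52 in cells with no Xist UMI), Nutf2-ps1 (2.10), Phpt1 (2.07), Myl10 (1.74, but −0.11 in cells with no Xist UMI), Wdr89 (1.62) and Bloc1s1 (1.61). Phpt1, a histidine phosphatase gene, was at 85.9 CPM in control and 102 CPM in the double mutant, against 47.5 and 43.9 CPM in the single mutants. The lists with the lowest departures were the dendritic (−2.89, or −0.93 with genes of at least 50 CPM), B cell (−2.00, or −0.52 class-standardised), stress and immediate early (−1.83), macrophage and monocyte (−1.09, but 1.04 with genes of at least 1 CPM) and quiescence lists (−1.05), and stem cell genes departed by 0.49 (percentile 100). With no replicate, no interaction was tested.

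**Figure D3:**
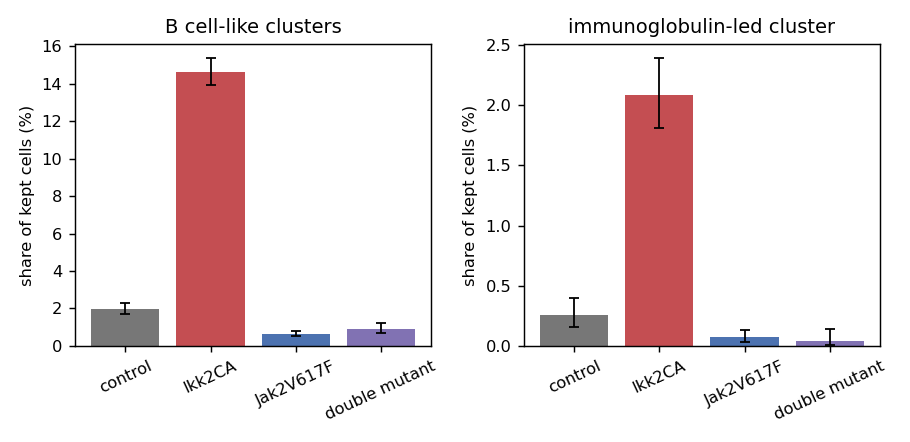
Share of kept cells in the B cell-like class and the immunoglobulin-led cluster per library, in percent, with exact binomial intervals. B cell-like cells were 14.6% of Ikk2CA and 1.97% of control.

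B cell-like cells were a far larger share of the Ikk2CA library than of the others. They were 1.97% of control cells (exact interval 1.68 to 2.30), 14.6% of Ikk2CA cells (13.9 to 15.4), 0.657% of Jak2V617F cells (0.531 to 0.804) and 0.930% of double-mutant cells (0.689 to 1.23), within a gate set to exclude mature lineages. An immunoglobulin-led cluster held 0.261%, 2.09%, 0.0706% and 0.0380%. Granulocyte-monocyte progenitor-like cells were 4.30%, 11.6%, 2.84% and 4.48%, although without the cells called doublets the Ikk2CA share was 3.42% against 4.12%, and clustered without sex-linked genes 3.76% against 4.07%. Megakaryocyte progenitor-like cells were 2.46%, 6.50%, 6.39% and 6.04%, and 1 cluster led by Apoe and Gp5 held most of them in control and Jak2V617F while another led by Pf4 did so in both Ikk2CA genotypes. At Leiden resolution 0.5 the Ikk2CA and double-mutant shares of that class were 0.0203% and 0.190% against 3.85% in control, and with cells thinned to the same depth the Jak2V617F share was 2.56% against 3.42%. Erythroid progenitor-like cells were 2.01%, 1.22%, 1.04% and 0.361%, and at Leiden resolution 0.5 the Ikk2CA and double-mutant shares were 8.08% and 6.81% against 2.58% in control. Dendritic cell-like cells were 0.521%, 0.770%, 0.318% and 0.0949%, but 0.795%, 19.4%, 0.650% and 5.85% when clustered without sex-linked genes, T, NK or innate lymphoid cell-like cells 0.261%, 0.872%, 0.558% and 0.0949%, and neutrophil-like cells 0.335%, 0.294%, 0.473% and 0.209%. Clusters of stem cell-like and lymphoid-primed cells parted by library and sex, so their shares were not compared there, and 66.6%, 61.6%, 47.2% and 86.7% of cells stayed in unnamed clusters.

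Within stem cell-like cells, the NF-κB targets Nfkbia, Relb and Ltb were higher in both genotypes with Ikk2CA. In granulocyte-monocyte and megakaryocyte progenitor-like clusters, the list median of the double mutant was close to that of Jak2V617F, without adjustment for the median gene. In the library sums that adjustment raised the double mutant's median over control but hardly moved that of Jak2V617F, so the closeness holds for unadjusted values only. When every cell was given the class of its nearest control cells, clustered without sex-linked genes, Nfkbia in stem cell-like cells was at 89.7 CPM in control, 469 CPM in Ikk2CA, 137 CPM in Jak2V617F and 289 CPM in the double mutant. Relb there was at 10.0, 48.5, 12.4 and 34.6 CPM and Ltb at 261, 1032, 265 and 695 CPM. Socs2 in the same cells was at 26.6, 52.3, 54.4 and 74.7 CPM and Fos at 89.7, 1070.4, 368 and 118 CPM. The stem cell factor Hlf was at 546, 257, 485 and 236 CPM in these cells, whereas Mecom was at 125, 115, 125 and 92.5 CPM. Among clusters of all libraries, the median log2 ratio of NF-κB targets in Ikk2CA against control was 0.87 in granulocyte-monocyte progenitor-like and 0.99 in megakaryocyte progenitor-like cells, against 0.33 and 0.18 in Jak2V617F and 0.20 and 0.21 in the double mutant. Stress and immediate early genes were at 1.52 and 1.73 in Ikk2CA, 0.57 and 0.60 in Jak2V617F, and 0.07 and −0.09 in the double mutant. For Ikk2CA and the double mutant the megakaryocyte values compared mostly the Pf4-led cluster with the Apoe-led cluster of control. The granulocyte-monocyte progenitor-like class of Ikk2CA was far smaller without called doublets, so these values do not separate changes within a class from its make-up. In megakaryocyte progenitor-like cells, Cish was at 7.93 CPM in control and 32.5 CPM in Jak2V617F, both mostly from the Apoe-led cluster, and at 10.6 and 9.86 CPM in Ikk2CA and the double mutant, mostly from the Pf4-led cluster. That assignment to control cells was chosen after the clusters had been seen.

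**Figure D4:**
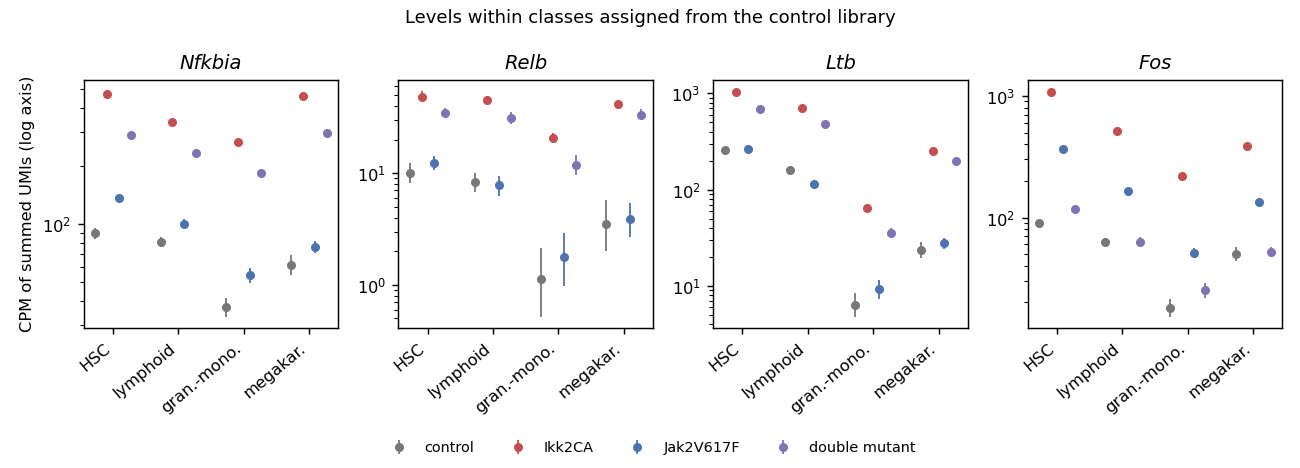
CPM of Nfkbia, Relb, Ltb and Fos (log axis) within stem cell-like, lymphoid-primed, granulocyte-monocyte and megakaryocyte progenitor-like cells assigned from the control library, with counting intervals. In stem cell-like cells Nfkbia was at 469 CPM in Ikk2CA and 89.7 CPM in control.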

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

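Tests chosen only after the results had been seen were the share of B cell UMIs inside the named clusters, the B cell-like share in the double mutant over Jak2V617F, and the immediate early list in the double mutant over Jak2V617F. The other tests were set before their results were seen, and for a pair of them the reading was changed afterwards, as said below.

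For 3 results an allele went with opposite directions in the presence and absence of the other allele, and none of these differences was tested, since each genotype had 1 library. The median log2 ratio of quiescence genes with Ikk2CA was 0.46 without Jak2V617F and −0.61 with it, a difference of −1.08. For stress and immediate early genes, it was 1.05 with Ikk2CA alone and −0.79 on the Jak2V617F background, a difference of −1.84. The same list with Jak2V617F was at 0.44 without Ikk2CA and −1.54 with it, a difference of −1.97. Per gene, both differences of the stress list are the same departure from additivity, and they part only as differences of medians. The quiescence list shares Btg2 with the stress list and comes from the same libraries. The 3 are therefore not separate lines of evidence.

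B cell genes were higher in the Ikk2CA library than in control (median log2 ratio 2.43), and none of the explanations tested was excluded. Without the B cell-like and immunoglobulin-led clusters the median was still 1.84, which met the bound set beforehand against such cells as the cause. But the clusters held a median of 91.8%, 94.9%, 86.2% and 92.1% of the list's UMIs in control, Ikk2CA, Jak2V617F and the double mutant. The remainder thus rose and fell with them, as RNA of such cells in other droplets would, so 1.84 does not decide. Of the 10 genes, 9 also name the clusters, but Igll1, which does not, had 96.7% of its Ikk2CA UMIs there. The share for Cd79b was lower, at 68.0%. Most of the list's UMIs in Ikk2CA thus lay in cells of these clusters, which does not show why such cells were there. Since the clusters gather cells that carry these genes, the median of 0.34 with the control library's class shares restates this and decides nothing further. Ly6a in B cell-like cells was 3.76 times as high in Ikk2CA as in control (interval 3.17 to 4.49). This met the bound set beforehand for a gate reached through more Sca-1. But Ly6a was 3.66 times as high in the double mutant (2.98 to 4.51), where B cell-like cells were 0.930% of the library and under 100 in number. That reading was therefore withdrawn after the double mutant had been seen. The B cell-like share in the double mutant over Jak2V617F was 1.42 (interval 0.981 to 2.02), so an effect of the Ikk2CA allele with either Jak2 allele and a property of the Ikk2CA pool cannot be told apart with 1 library per genotype.

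Immediate early genes were higher in both single mutants than in control but not in the double mutant. The list's median log2 ratio in the double mutant over Jak2V617F, −0.79, restates this pattern, so it tests no effect of the alleles. A difference in handling that reached cells of the 3 classes compared may account for the pattern. The departure from additivity was −1.24 in B cell-like, −2.82 in granulocyte-monocyte progenitor-like and −2.73 in megakaryocyte progenitor-like cells. An interaction of the alleles in these classes would give the same. B cell-like cells of the double mutant were under 100, the least number set for class comparisons. The granulocyte-monocyte progenitor-like class of Ikk2CA depended on the doublet calls, and most cells lay outside these classes. A heat shock response cannot be told apart, because only 3 of its members were measured and their median departure was −0.22. The labels give no date or batch, and this contrast sets control and the double mutant against both single mutants, so any shared processing of those pairs stays open.

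The 6 genes with the most positive departure from additivity, among them Nutf2-ps1, Phpt1 and Bloc1s1, had a median departure of 1.91. With the control library's class shares the median was 1.86, which argues against the shares of the larger named classes as the whole cause. Cells of unnamed clusters and small classes were pooled there, so shares within that pool were not tested. Sex of the pooled mice is argued against as the whole cause by 1.63 in cells with at least 5000 UMIs and no Xist UMI. A difference between libraries that reached cells of the classes compared may account for it. The median was 1.49 in B cell-like, 1.53 in granulocyte-monocyte progenitor-like and 1.57 in megakaryocyte progenitor-like cells. The genes were chosen by this departure in the same libraries, so a positive value in subsets of those cells was partly fixed in advance. B cell-like cells of the double mutant were under 100, the least number set for class comparisons. The class medians do not speak for Emcn (2.12 over all cells, but 0.34, 0.69 and 0.78 in these classes) or Myl10 (1.74, but 0.81, 1.42 and 0.98). In cells with no Xist UMI Myl10 departed by −0.11. That setting also kept only cells with at least 5000 UMIs, so sex and depth both stay open for Myl10. An interaction of the alleles in every class would give the same values and stays open, untested.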

How the results depend on the processing

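Chosen after the results had been seen were the alternatives with top Scrublet scores left out, in cells with no Xist UMI, with lineage clusters left out, when clustered without sex-linked genes and with control clusters without sex-linked genes, and the rest were set beforehand. Of 2471 alternative values of list and all-gene medians, 2295 stayed within the interval or step set for them and 171 moved past it. In 236 the sign differed from the main value, and 5 of these, whose main interval lay away from 0, are marked as reversed below. For a list, the interval was that of the main median, taken from the ranked values of its members. In lists of few members it spans all or nearly all of these values. Staying within it therefore says little there. For ratios of class shares to control the numbers that stayed, moved and reversed were 153, 65 and 13 of 231, and for named genes 785, 423 and 5 of 1213. Counts of genes stayed within 1.5 times in 76 of 120, and correlations were kept in 30 of 36. Below are the values that moved or reversed, apart from named genes that moved by up to 1.5 times without reversing. List and gene values are log2, and class shares are ratios to control. The cause of these shifts was not tested.

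With TMM factors, values were all genes 0.014, interferon-gamma GTPases 0.047, haematopoietic stem cell genes −0.85, B cell genes 2.68, S phase genes 0.28, G2 and M phase genes 0.39, MYC and ribosome biogenesis genes 0.28, oxidative phosphorylation genes 0.44, heme and iron genes 0.12 and genes at most 0.5 times as high 123 for Ikk2CA over control. All genes 0.014, STAT5 and JAK-STAT feedback genes −0.062, interferon-stimulated genes −0.41, haematopoietic stem cell genes −0.16, granulocyte-monocyte genes −0.18, B cell genes −1.31, S phase genes 0.32, G2 and M phase genes 0.16, quiescence genes −0.29, MYC and ribosome biogenesis genes 0.60, inflammatory cytokines and receptors −0.26, niche adhesion and homing genes −0.22, unfolded protein response genes 0.14, oxidative phosphorylation genes 0.55, haematopoietic cytokine receptors −0.25, genes at least 2 times as high 122 and genes at most 0.5 times as high 91 for the double mutant over control. All genes 0.028, MHC class I presentation 0.29, haematopoietic stem cell genes −0.38, S phase genes 0.33, G2 and M phase genes 0.18, quiescence genes −0.37, MYC and ribosome biogenesis genes 0.44, inflammatory cytokines and receptors −0.025, niche adhesion and homing genes −0.26, unfolded protein response genes 0.21, glycolysis genes 0.36, oxidative phosphorylation genes 0.49, heme and iron genes 0.18, haematopoietic cytokine receptors −0.064 and genes at most 0.5 times as high 30 for the double mutant over Jak2V617F.

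With median-of-ratios size factors, values were all genes 0.044, interferon-gamma GTPases 0.078, haematopoietic stem cell genes −0.82, neutrophil genes −0.40, B cell genes 2.71, S phase genes 0.31, G2 and M phase genes 0.42, MYC and ribosome biogenesis genes 0.31, oxidative phosphorylation genes 0.47, heme and iron genes 0.15 and genes at most 0.5 times as high 113 for Ikk2CA over control. All genes 0.085, STAT5 and JAK-STAT feedback genes 0.0094, interferon-stimulated genes −0.34, MHC class I presentation 0.35, haematopoietic stem cell genes −0.091, granulocyte-monocyte genes −0.11, B cell genes −1.24, S phase genes 0.39, G2 and M phase genes 0.23, quiescence genes −0.21, MYC and ribosome biogenesis genes 0.67, inflammatory cytokines and receptors −0.19, niche adhesion and homing genes −0.15, stress and immediate early genes 0.17, unfolded protein response genes 0.21, glycolysis genes 0.46, oxidative phosphorylation genes 0.62, haematopoietic cytokine receptors −0.17, genes at least 2 times as high 143 and genes at most 0.5 times as high 79 for the double mutant over control. Glycolysis genes 0.37 and oxidative phosphorylation genes 0.15 for the double mutant over Ikk2CA. All genes 0.10, interferon-stimulated genes −0.34, MHC class I presentation 0.36, haematopoietic stem cell genes −0.31, lymphoid priming genes −0.16, megakaryocyte and platelet genes −0.016, B cell genes 0.73, S phase genes 0.40, G2 and M phase genes 0.25, quiescence genes −0.30, MYC and ribosome biogenesis genes 0.51, apoptosis regulators 0.16, inflammatory cytokines and receptors 0.046, niche adhesion and homing genes −0.19, unfolded protein response genes 0.28, glycolysis genes 0.43, oxidative phosphorylation genes 0.56, heme and iron genes 0.25, haematopoietic cytokine receptors 0.0074, genes at least 2 times as high 101 and genes at most 0.5 times as high 27 for the double mutant over Jak2V617F.

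With genes of at least 1 CPM, values were genes at least 2 times as high 445 and genes at most 0.5 times as high 921 for Ikk2CA over control. Genes at least 2 times as high 96 and genes at most 0.5 times as high 172 for Jak2V617F over control. Genes at least 2 times as high 161 and genes at most 0.5 times as high 839 for the double mutant over control. T, NK and innate lymphoid genes −1.33, genes at least 2 times as high 120 and genes at most 0.5 times as high 518 for the double mutant over Ikk2CA. Genes at least 2 times as high 137 and genes at most 0.5 times as high 488 for the double mutant over Jak2V617F.

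With genes of at least 50 CPM, values were all genes −0.079, interferon-stimulated genes −0.32, heme and iron genes 0.051, genes at least 2 times as high 77 and genes at most 0.5 times as high 52 for Ikk2CA over control. Genes at least 2 times as high 9 and genes at most 0.5 times as high 10 for Jak2V617F over control. All genes −0.035, interferon-stimulated genes −0.23, heme and iron genes 0.054, genes at least 2 times as high 24 and genes at most 0.5 times as high 26 for the double mutant over control. Genes at least 2 times as high 5 and genes at most 0.5 times as high 59 for the double mutant over Ikk2CA. All genes −0.014, interferon-stimulated genes −0.36, genes at least 2 times as high 22 and genes at most 0.5 times as high 15 for the double mutant over Jak2V617F. Haematopoietic cytokine receptors 0.41 for the departure from additivity.

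With no low-count filter, values were genes at least 2 times as high 1482 and genes at most 0.5 times as high 2239 for Ikk2CA over control. Genes at least 2 times as high 985 and genes at most 0.5 times as high 998 for Jak2V617F over control. All genes −0.35, T, NK and innate lymphoid genes −0.65, genes at least 2 times as high 679 and genes at most 0.5 times as high 2599 for the double mutant over control. T, NK and innate lymphoid genes −1.56, genes at least 2 times as high 848 and genes at most 0.5 times as high 2030 for the double mutant over Ikk2CA. All genes −0.32, T, NK and innate lymphoid genes −0.61, genes at least 2 times as high 647 and genes at most 0.5 times as high 2282 for the double mutant over Jak2V617F. Pearson correlations 0.289 for the Ikk2CA effect in both Jak2 backgrounds, 0.119 for the Jak2V617F effect in both Ikk2 backgrounds, −0.156 for the Ikk2CA main effect against Jak2V617F main effect.

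Over all deposited barcodes, values were B cell genes 2.27, Hbb-bs 3.61, Hba-a2 3.22, Hba-a1 3.61 and Prg2 2.78 for Ikk2CA over control. Hbb-bs −0.30 (reversed) and Hba-a1 −0.67 (reversed) for Jak2V617F over control. Hba-a2 1.45 and Hbb-bs 1.39 for the double mutant over control. Prg2 −5.69, Hbb-bs −1.92 and Hba-a2 −0.66 for the departure from additivity.

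With Scrublet-called doublets left out of the sums, values were B cell genes 2.37 for Ikk2CA over control.

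As a mean over cells scaled to the same total, values were neutrophil genes −0.22, B cell genes 2.83, G2 and M phase genes 0.34 and Prg2 4.93 for Ikk2CA over control. B cell genes −1.61, oxidative phosphorylation genes 0.011, Hbb-bs 3.16, Hba-a1 2.60 and Jchain −2.21 for Jak2V617F over control. Ccl5 1.62 and Hba-a2 2.82 for the double mutant over control. Neutrophil genes −0.19, G2 and M phase genes −0.38 and Prg2 −7.44 for the double mutant over Ikk2CA. B cell genes 0.019 for the double mutant over Jak2V617F. Interferon-stimulated genes −0.19, neutrophil genes −0.80, B cell genes −2.80, Prg2 −8.98 and Hba-a2 −5.22 for the departure from additivity.

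With class-standardised sums, values were haematopoietic stem cell genes −0.89, neutrophil genes −0.27, B cell genes 0.34, S phase genes −0.076, G2 and M phase genes −0.10 (reversed) and genes at most 0.5 times as high 184 for Ikk2CA over control. Granulocyte-monocyte genes −0.22, B cell genes −0.43, G2 and M phase genes 0.089, Vpreb3 −0.61, Cd79a −0.61, Igll1 −0.43, Ebf1 −0.31, Mzb1 −0.55, Vpreb1 −0.24 and Bfsp2 −0.28 for Jak2V617F over control. B cell genes −0.47, Vpreb3 −0.79 and Mzb1 −0.92 for the double mutant over control. Haematopoietic stem cell genes 0.30, neutrophil genes −0.34, B cell genes −0.98, S phase genes 0.20, G2 and M phase genes 0.087 (reversed), oxidative phosphorylation genes 0.16, Mzb1 −3.32 and Vpreb3 −1.06 for the double mutant over Ikk2CA. B cell genes −0.010 (reversed) for the double mutant over Jak2V617F. Interferon-stimulated genes −0.15, neutrophil genes −0.52, B cell genes −0.52 and G2 and M phase genes −0.040 for the departure from additivity. Pearson correlations −0.171 for the Ikk2CA main effect against Jak2V617F main effect.

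At Leiden resolution 0.5, values were the erythroid progenitor-like share 3.13 (reversed), the granulocyte-monocyte progenitor-like share 1.93, the megakaryocyte progenitor-like share 0.00527 (reversed) and G2 and M phase genes within granulocyte-monocyte progenitor-like cells −0.83 (reversed) for Ikk2CA over control. The HSC-like share 2.68, the lymphoid-primed progenitor-like share 1.11, interferon-stimulated genes within granulocyte-monocyte progenitor-like cells 0.21 and G2 and M phase genes within granulocyte-monocyte progenitor-like cells −0.27 for Jak2V617F over control. The erythroid progenitor-like share 2.64 (reversed), the granulocyte-monocyte progenitor-like share 0.676, the megakaryocyte progenitor-like share 0.0493 (reversed), stress and immediate early genes within granulocyte-monocyte progenitor-like cells −0.10 and G2 and M phase genes within granulocyte-monocyte progenitor-like cells −0.17 for the double mutant over control. G2 and M phase genes within granulocyte-monocyte progenitor-like cells 0.67 (reversed) for the double mutant over Ikk2CA. Interferon-stimulated genes within granulocyte-monocyte progenitor-like cells −0.53 and MYC and ribosome biogenesis genes within granulocyte-monocyte progenitor-like cells 0.25 for the double mutant over Jak2V617F.

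At Leiden resolution 2, values were the dendritic cell-like share 9.77, the lymphoid-primed progenitor-like share 0.556, the mast cell or basophil-like share 0.104 (reversed) and the megakaryocyte progenitor-like share 3.80 for Ikk2CA over control. The HSC-like share 3.00 for Jak2V617F over control. The dendritic cell-like share 1.35 (reversed), the granulocyte-monocyte progenitor-like share 1.89, the lymphoid-primed progenitor-like share 0.404, the mast cell or basophil-like share 0.287 (reversed) and the megakaryocyte progenitor-like share 4.08 for the double mutant over control.

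With cells called doublets by Scrublet left out before clustering, values were the HSC-like share 0.0311 and the granulocyte-monocyte progenitor-like share 0.829 (reversed) for Ikk2CA over control. The HSC-like share 4.64 and the lymphoid-primed progenitor-like share 1.13 for Jak2V617F over control. The granulocyte-monocyte progenitor-like share 0.686 and the megakaryocyte progenitor-like share 3.21 for the double mutant over control.

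With control clusters and nearest neighbours, values were the HSC-like share 1.19 (reversed), the erythroid progenitor-like share 0.320, the granulocyte-monocyte progenitor-like share 1.43 and the megakaryocyte progenitor-like share 1.46 for Ikk2CA over control. The HSC-like share 2.62 and the erythroid progenitor-like share 0.220 for Jak2V617F over control. The HSC-like share 1.24 (reversed) and the granulocyte-monocyte progenitor-like share 0.793 for the double mutant over control.

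With cells thinned to one depth, values were the erythroid progenitor-like share 0.803, the granulocyte-monocyte progenitor-like share 2.06, the lymphoid-primed progenitor-like share 0.0227 and the megakaryocyte progenitor-like share 3.13 for Ikk2CA over control. The HSC-like share 2.34, the T, NK or innate lymphoid cell-like share 1.29, the lymphoid-primed progenitor-like share 1.07 and the megakaryocyte progenitor-like share 0.749 (reversed) for Jak2V617F over control. The HSC-like share 0.0640, the granulocyte-monocyte progenitor-like share 1.69, the lymphoid-primed progenitor-like share 0.0693 and the megakaryocyte progenitor-like share 3.25 for the double mutant over control.

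With top Scrublet scores left out, values were neutrophil genes −6.09, Hbb-bs 1.14, the erythroid progenitor-like share 0.446, the granulocyte-monocyte progenitor-like share 1.56, the megakaryocyte progenitor-like share 4.33 and the neutrophil-like share 0.118 for Ikk2CA over control. The HSC-like share 2.94 and the granulocyte-monocyte progenitor-like share 0.525 for Jak2V617F over control. Hbb-bs −0.57 (reversed), Jchain −9.25, the granulocyte-monocyte progenitor-like share 0.711, the immunoglobulin-led share 0 and the megakaryocyte progenitor-like share 4.58 for the double mutant over control. Neutrophil genes 5.23, Prg2 −8.32 and Jchain −11.06 for the double mutant over Ikk2CA. Neutrophil genes 4.91, Prg2 −5.26, Hbb-bs −4.43 and Hba-a2 −3.55 for the departure from additivity.

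In cells with no Xist UMI, all with at least 5000 UMIs, values were mast cell, basophil and eosinophil genes 1.00, neutrophil genes −1.39, B cell genes 2.14, Prg2 4.68 and Ccl5 4.37 for Ikk2CA over control. Neutrophil genes −0.085, B cell genes −2.34 and MYC and ribosome biogenesis genes 0.20 for Jak2V617F over control. Stress and immediate early genes −0.33, Ccl5 3.82, Hbb-bs −0.92 (reversed), Jchain −2.49, Paqr5 −3.34, Wfdc17 −3.40 and genes at most 0.5 times as high 306 for the double mutant over control. Neutrophil genes 0.45, B cell genes −3.71, G2 and M phase genes −0.19 and oxidative phosphorylation genes 0.13 for the double mutant over Ikk2CA. B cell genes 0.83 and genes at most 0.5 times as high 152 for the double mutant over Jak2V617F. Neutrophil genes 0.53, B cell genes −1.31, Emcn 1.52, Myl10 −0.11 (reversed), Hbb-bs −8.09 and Hba-a2 −8.02 for the departure from additivity.

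With lineage clusters left out, values were neutrophil genes −2.44, B cell genes 2.10, G2 and M phase genes 0.030, Hbb-bs 4.15, Hba-a2 3.90 and Ccl5 3.73 for Ikk2CA over control. Neutrophil genes −1.34, B cell genes −1.57, S phase genes 0.17 and Car1 −0.57 for Jak2V617F over control. Neutrophil genes −2.54, B cell genes −1.16 and Ccl5 2.86 for the double mutant over control. Granulocyte-monocyte genes −0.50, megakaryocyte and platelet genes 0.026, B cell genes −3.58, G2 and M phase genes −0.10, MYC and ribosome biogenesis genes 0.22, Socs2 1.97, Prg2 −7.83, genes at least 2 times as high 16 and genes at most 0.5 times as high 105 for the double mutant over Ikk2CA. Neutrophil genes 1.24, B cell genes −1.66, MYC and ribosome biogenesis genes 0.084, Prg2 −8.62, Hbb-bs −3.97 and Hba-a2 −3.35 for the departure from additivity. Pearson correlations 0.105 for the Jak2V617F effect in both Ikk2 backgrounds, −0.121 for the Ikk2CA main effect against Jak2V617F main effect.

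When clustered without sex-linked genes, values were the HSC-like share 0.00656, the dendritic cell-like share 24.4, the erythroid progenitor-like share 0.208 and the granulocyte-monocyte progenitor-like share 0.924 (reversed) for Ikk2CA over control. The HSC-like share 1.20, the erythroid progenitor-like share 0.240, the lymphoid-primed progenitor-like share 0.537 and the megakaryocyte progenitor-like share 1.41 for Jak2V617F over control. The HSC-like share 0.235, the dendritic cell-like share 7.36 (reversed), the granulocyte-monocyte progenitor-like share 0.727 and the lymphoid-primed progenitor-like share 0.127 for the double mutant over control.

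With control clusters without sex-linked genes, values were the HSC-like share 0.396, the erythroid progenitor-like share 0.217, the granulocyte-monocyte progenitor-like share 1.29, the lymphoid-primed progenitor-like share 0.400 and the megakaryocyte progenitor-like share 1.51 for Ikk2CA over control. The HSC-like share 1.32, the erythroid progenitor-like share 0.197, the lymphoid-primed progenitor-like share 0.591 and the megakaryocyte progenitor-like share 1.19 for Jak2V617F over control. The HSC-like share 0.997, the granulocyte-monocyte progenitor-like share 0.735, the lymphoid-primed progenitor-like share 0.524 and the megakaryocyte progenitor-like share 1.67 for the double mutant over control.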

Other observations

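The histone genes and the clusters described here were chosen after the results had been seen, and no explanation of them was tested. Replication-dependent histone genes, 37 in all, had a median log2 ratio of 1.59 in Ikk2CA, 0.63 in Jak2V617F and 1.18 in the double mutant against control. In cells with no Xist UMI the values were 1.495, 0.50 and 1.17.

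A cluster led by Nr4a2, Ccl4, Nr4a1 and Fos held 23.3% of Ikk2CA cells against 0.0248%, 0.120% and 0.532% of control, Jak2V617F and double-mutant cells. Another, led by Pdcd1lg2 and Ltb, held 39.2% of double-mutant cells, 4.71% of Ikk2CA cells, 0.273% of control cells and 0.247% of Jak2V617F cells. Clusters mostly of a single library describe that library and are not called cell types here. Mast cell or basophil-like cells were 0.0248%, 0.162%, 0.0212% and 0.588% of control, Ikk2CA, Jak2V617F and the double mutant, and at Leiden resolution 2 the shares in Ikk2CA and the double mutant were below control.

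Some of the lists not described above are given as median log2 ratios of Ikk2CA, Jak2V617F and the double mutant over control. They were 0.26, −0.17 and −0.11 for the unfolded protein response (the last 0.14 with TMM factors), 0.52, 0.01 and 0.11 for MHC class II (the middle value −0.086 in cells with no Xist UMI, the last −0.24 with genes of at least 1 CPM), and −0.20, 0.07 and −0.57 for interferon-gamma GTPases (the first 0.047 with TMM factors, the middle value −0.12 with genes of at least 50 CPM). Oxidative phosphorylation genes were at 0.19, 0.05 and 0.30, glycolysis genes at −0.34, 0.04 and 0.14, S phase genes at 0.03, 0.12 and 0.07 (the first −0.076 with class-standardised sums), and G2 and M phase genes at 0.15, 0.02 and −0.09 (the first −0.10 with class-standardised sums, the last 0.16 with TMM factors). Cytokine receptors were at −0.55, −0.16 and −0.50, and niche adhesion genes at −0.48, 0.01 and −0.47. Niche adhesion and homing genes in Jak2V617F were at −0.15 with genes of at least 50 CPM. Neutrophil genes were at −0.67, 0.13 and −0.63, but at −2.44, −1.34 and −2.54 with lineage clusters left out, and in Jak2V617F at −0.085 in cells with no Xist UMI.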
